A study of Caenorhabditis elegans with 21 samples.

How the data were processed

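Small RNAs of whole L4 worms grown at 15 °C on NA22 bacteria were treated with an RNA 5′ polyphosphatase, which lets small RNAs with a 5′ triphosphate enter a library, and were sequenced after preparation with the QIAseq miRNA kit, as the labels state. The submitters' processing notes list cutadapt 2.3, Bowtie 1.2.3, SAMtools 1.9 and HTSeq 0.11.2 and the ce11 assembly, without saying what each tool did. The strand setting, any length filter, the handling of reads with several positions, the source of the unnamed intervals and any removal of duplicate reads are not given in the sources used here. The deposited table holds counts per feature and library, whole numbers that were used as deposited, per the submitters' processing notes from HTSeq.

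The table has 75393 features, of which 20134 are gene identifiers and 55259 are unnamed genomic intervals given by coordinates. The annotation used here (Ensembl WBcel235, the same assembly as ce11) contains 20055 of the identifiers, of which 19850 are protein-coding genes, 198 pseudogenes and 7 lincRNAs, and lacks 79. The intervals span 10 to 37898 bases (median 139). By this annotation 21340 are intergenic, 31178 lie within or across an intron and 2741 overlap an exon. The table also gives the reads that fell in no feature, which made up 63.8% ± 7.85 (SD, n = 9) of all reads counted in wild type. They were left out of the tests of features and lists. The tests of shares and an alternative scaling to all reads counted included them.

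All 21 libraries entered 1 edgeR quasi-likelihood fit with a mean per genotype. Trimmed mean of M values (TMM) scaling and the filterByExpr filter of edgeR were applied, which kept 5038 features, 4543 genes and 495 intervals, with 92.2% of the feature counts. Benjamini-Hochberg adjustment was made over the features tested, and a feature was called at an adjusted p under 0.05. Library-normalised counts (CPM) were computed here from the counts with the TMM scaling, and values are means ± SD over libraries. Log2 fold changes carry a standard error (SE) from the fit. This design and the gene lists, rule for named features and alternatives were fixed before the data were examined, except the alternatives said to be chosen after seeing the data.

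Gene lists were written from general knowledge of the field. They cover targets of the ERGO-1 Argonaute with 26G RNAs, germline genes silenced by WAGO Argonautes or piRNAs, spermatogenesis genes, germline and maternal genes of the CSR-1 type, histones, cytosolic ribosomal proteins, and small RNA pathway genes. Others cover cuticle collagens, muscle, neuron and intestine genes, and transposons, microRNAs, heterochronic microRNAs, the mir-35 family and piRNAs. All pseudogenes and all intervals were tested as 2 further sets, which are not among the lists fixed before the data were examined. Of the written names, sdg-1 was not found in the annotation. A list with at least 5 tested members was tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over all lists and comparisons. Counts are also given adjusted over the list alone.

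Features were named by a fixed rule. For each mutant it takes the 6 largest rises and 6 largest falls among called features with a mean of at least 10 CPM in the higher group and every mutant library beyond every wild-type library. It adds the 2 members with the smallest p of each list with at least 5 tested members, and dpf-3, mut-2 and mut-7. For the other comparisons it takes up to 3 rises and 3 falls. A fold against a group without a count is a lower bound, computed with 3 counts over the group, and a fold against 1 to 3 counts is a ratio with an exact 95% interval. Both cover counting error only, since it is not given whether reads are independent molecules.

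Shares of counts were compared by 2-sided exact permutation tests of the difference in means, adjusted over 5 classes and the comparisons with wild type. Agreement between mutants was set against 20 simulations of unchanged groups compared with the same controls, against the overlap of independent calls, and against comparisons in which wild type was split so that no library served both mutants. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run as alternatives to edgeR 4.0.16 in R 4.3.3. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. In simulated counts with the spread of the fit over 5038 features, 4-fold changes were called in 80.3% of cases for 3 libraries at the depth of DPF-3 S784A and 71.8% at that of mut-2, 2-fold changes in 21.9% and 19.7%, and 3.05% and 2.48% of calls were false. With the spread of the fit with wild type as 2 sets these values were 80.3% and 82.5% for 4-fold changes, 60.7% and 39.4% for 2-fold changes, and 4.68% and 3.97% of calls were false. Both simulations gave an unchanged feature the same mean in all libraries. They therefore do not cover calls that arise from the difference between the wild-type sets described below.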

Results

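Small RNAs of whole L4 worms of Caenorhabditis elegans were counted in 21 libraries of 5 genotypes. Wild type had 9 libraries, named A to I, and 3 libraries each, A to C, came from a dpf-3 null mutant, from DPF-3 S784A (a single amino acid change in the protein), from mut-2(ne3370) and from mut-7(ne4255). dpf-3 encodes a dipeptidyl peptidase family protein, mut-2 (also rde-3) a nucleotidyltransferase and mut-7 a protein of the exonuclease family, and the mut genes serve the amplification of silencing small RNAs. Counts in features ranged from 40693 to 583038 per library, with means of 377430 in wild type, 179300 in the dpf-3 null, 90622 in DPF-3 S784A, 44346 in mut-2 and 79581 in mut-7. All reads counted, those in no feature included, ranged from 366911 to 1448677. At least 1 count was seen in 28149 features, 12094 of them intervals. A level of 3 counts equalled between 6.07 CPM (wild type G) and 50.7 CPM (mut-2 A). The sources used here do not say that the replicates are separate cultures, so the p-values measure only the spread between these samples.

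The 9 wild-type libraries fell into 2 sets, A to F and G to I, which the labels do not separate. Of 5038 features tested, 905 were higher and 1693 lower in G to I. This difference enters the spread of the fit with 1 wild-type group, which sets the SE and p of every comparison, also those between mutants. The common dispersion of that fit was 0.0947, against 0.00466 with wild type as 2 sets. In G to I 459 of 495 intervals, 39 of 44 histone genes and 18 of 20 ERGO-1 targets were lower, with median log2 fold changes of -1.05, -1.44 and -1.67. So were 7 of 7 collagens and 35 of 48 pseudogenes (8 higher). Each comparison with wild type is therefore given with all 9 libraries, with lists also against each set and, for genes whose fold differed most between the sets, the fold against each. The labels do not place the mutant libraries with either set. In the count table A to F come before the dpf-3 genotypes and G to I before the mut genotypes, and this order was not used to place any library.

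The genes that the genotypes target came first. Small RNA counts of dpf-3 (WBGene00001056; ce11, chromosome I, 6838354 to 6843343, plus strand) fell from 102 CPM ± 27.1 (n = 9) in wild type to 8.84 ± 4.12 (n = 3) in the null, a log2 fold change of -3.33 (SE 0.39, adjusted p = 3.89e-07) that rests on 5 counts. They were 139 CPM ± 26.2 in DPF-3 S784A (adjusted p = 0.194), 136 ± 36.5 in mut-2 (adjusted p = 0.221) and 137 ± 26.6 in mut-7 (adjusted p = 0.138), n = 3 each, and these differences from wild type did not pass the test. Against G to I alone dpf-3 was called higher in S784A (log2 0.81, adjusted p = 0.0216), and against A to F it was not (log2 0.15, adjusted p = 0.736). The mut-2 gene (chromosome I, 6356614 to 6358411) had 34 counts in wild type, 2 in mut-2 and 13 in mut-7 and was too low to be tested. Counts of mut-7 (WBGene00003504; chromosome III, 9539031 to 9542380, minus strand) rose from 254 CPM ± 32.1 (n = 9) in wild type to 668 ± 97.5 in mut-2 (adjusted p = 1.29e-07) and 668 ± 54.2 in mut-7 (adjusted p = 3.75e-08), n = 3 each. The rise in mut-2 was lost when libraries were scaled to all reads counted. These are small RNAs, not messenger RNA, so they do not test the mutations.

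Unnamed intervals held 19.9% ± 2.6 of feature counts in wild type (SD, n = 9; 21.6% ± 0.219 in A to F and 16.4% ± 0.169 in G to I). Their share was 6.99% ± 0.0174 in the dpf-3 null, 8.82% ± 0.11 in DPF-3 S784A, 6.19% ± 0.606 in mut-2 and 3.49% ± 0.402 in mut-7 (SD, n = 3 each). Within feature counts protein-coding genes made up the difference, with 76.5% of feature counts in wild type and 89.5%, 87.8%, 92.9% and 95.4% in the mutants in that order. Of all reads counted, genes held less in each mutant, 19.5%, 16.2%, 9.12% and 13.4% in the same order. In wild type they held 29.1% of all reads (24.3% in A to F and 38.7% in G to I). Of feature counts pseudogenes held 3.53% ± 0.401 in wild type, 0.845% ± 0.261 in mut-2 and 1.02% ± 0.0485 in mut-7, against 3.43% ± 0.260 in the dpf-3 null and 3.35% ± 0.128 in DPF-3 S784A. Each of the 4 interval shares and the 2 pseudogene shares of the mut genotypes lay below all 9 wild-type libraries (exact permutation p = 0.00909, the smallest that 220 splits allow, adjusted p = 0.0121). The exact permutation p for pseudogenes was 0.682 in the dpf-3 null and 0.473 in DPF-3 S784A, but the sets differed, with 3.78% in A to F and 3.02% in G to I. Both dpf-3 means lay below A to F (exact p = 0.0714 for the null and 0.0238 for S784A) and above G to I (exact p = 0.1 for each). Against A to F alone the interval shares had an exact p of 0.0238, the smallest possible, and against G to I the smallest exact p possible was 0.1.

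**Figure D1:**
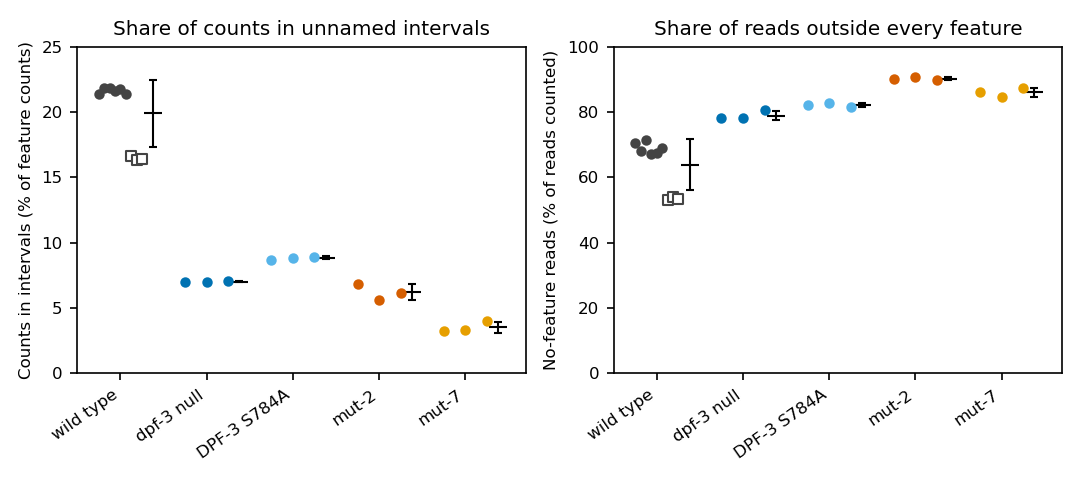
Percent of feature counts in unnamed intervals and percent of all reads counted that fell in no feature, per library. Filled circles are libraries, open squares wild type G to I, and the bar is the mean ± SD of each genotype. Interval shares were 19.9% in wild type and 3.49% to 8.82% in the mutants.

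The comparison of the dpf-3 null with wild type asks which small RNAs change without DPF-3. Small RNAs of all 7 tested cuticle collagens and of 7 of 9 tested germline genes silenced by WAGO Argonautes fell, with medians of -4.23 and -1.83 (log2). The table has 170 collagens, and all but these 7 were too low to be tested. High counts in wild type alone are enough to pass the filter. In each comparison the 7 therefore do not stand for collagens as a class. col-71 (II, 3500077 to 3502570) fell from 1531 CPM ± 453 to 34.9 ± 12 and saeg-2 (WBGene00011964; III, 9240363 to 9242514) from 5151 ± 1069 to 299 ± 70.3, which is 17.1-fold (log2 -4.10, SE 0.32, adjusted p = 3.31e-09; n = 3 and 9 throughout). C38D9.2 (WBGene00008010; V, 17567150 to 17571742) fell from 5302 CPM ± 1818 to 346 ± 40.8, and the eri-6 helicase gene of the small RNA pathway (I, 4457375 to 4469460) 4.99-fold from 10329 ± 2241 to 2071 (log2 -2.32, SE 0.28). Of 495 intervals 399 fell and 8 rose, with a median of -2.73. An intergenic interval on chromosome III (6630737 to 6631713, plus strand) had 292 CPM ± 123 in wild type and no count in the null, at least 44.1-fold lower, and an intergenic interval on chromosome V (17126624 to 17128176, minus strand) was at least 39.2-fold lower. B0261.8 (I, 5271265 to 5272041) had 3 counts against 2571, a ratio of 201 (95% interval 68.7 to 975). Against G to I alone the 2 intervals were at least 24.3-fold and 23.9-fold lower and the ratio of B0261.8 was 101 (95% interval 34.2 to 489).

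Among the other groups 20 of 48 pseudogenes fell and 1 rose (median -1.30). Single members fell in lists that were not lower as a whole. Among them were the linker histone gene his-24 (WBGene00001898, X, 14490094 to 14491119), from 9412 CPM ± 3115 to 1278 (log2 -2.88, SE 0.45, adjusted p = 1.8e-05), his-61 (log2 -3.72), the ERGO-1 target C08F11.7 (IV, 13637275 to 13638666, log2 -4.20) and rpl-11.2 (log2 -2.63). The ERGO-1 target F14F7.5 was higher, at 142 CPM ± 37.0 against 48.5 ± 37.0 in wild type. That call was lost against G to I, with DESeq2 size factors, with all reads counted and without null B or C. Of the neuron genes, the neuropeptide processing gene egl-21 (log2 -2.66) and ida-1 fell, and the call of ida-1 was lost without any 1 null library. egl-21 had 21.4 CPM in the null, 193 in A to F and 37.3 in G to I, against which it was too low to be tested. The largest rises were smaller, led by lsl-1 (WBGene00009937; I, 9901076 to 9902950) from 61.7 CPM ± 34.0 to 261 ± 37.8 (log2 2.16, SE 0.31, adjusted p = 6.59e-06), mai-2 (1.72), zipt-11 (1.64), an intergenic interval on X (17400536 to 17400628; 1.55), spt-4 (1.55) and rps-30 (1.54). The folds against A to F and G to I were 3.25 and 9.02 for lsl-1, 2.26 and 4.82 for spt-4, 18.9 and 8.40 for C38D9.2, 16.5 and 7.39 for his-61 and 8.91 and 4.34 for his-24. Histones had 5 genes higher and 4 lower of 44 tested, ERGO-1 targets 2 and 1 of 20 and ribosomal proteins 8 and 1 of 55. There were 18 higher and 4 lower of 51 tested small RNA pathway genes, 10 and 2 of 41 in the CSR-1 type list and 0 and 2 of 5 neuron genes.

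In total 671 features were higher and 1158 lower in the null. The number higher fell without any 1 library, to 224, 219 and 432 without null A, B and C and to 362 to 401 without each of the 9 wild-type libraries, while 1056 to 1151 were lower. With wild type as 2 sets 1319 were higher and 1323 lower. Adjusted over the list alone, the counts higher and lower were 0 and 7 for collagens, 1 and 7 for WAGO genes, 11 and 409 for intervals. They were 1 and 21 for pseudogenes, 4 and 4 for histones, 0 and 1 for ERGO-1 targets, 5 and 1 for ribosomal proteins, 18 and 4 for small RNA pathway genes, 9 and 2 for the CSR-1 type list and 0 and 2 for neuron genes. By camera the collagen (adjusted p = 1.27e-05), WAGO (6.14e-05), interval (3.76e-40) and pseudogene (0.000859) sets were lower relative to other features. The ribosomal (0.00312), pathway (0.00581) and CSR-1 type (0.0169) lists were higher. With an estimated correlation none passed, with adjusted p = 0.231 for collagens, 0.200 for WAGO genes, 0.231 for intervals, 0.461 for pseudogenes. It was 0.231 for ribosomal proteins, 0.200 for pathway genes and 0.182 for the CSR-1 type list. ERGO-1 targets (median 0.48, adjusted p = 0.0776), histones (median 0.35, adjusted p = 0.158) and neuron genes (median -0.51, adjusted p = 0.788) did not pass at the preset correlation.

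The rises depended on the scaling and on the wild-type set. DESeq2 size factors gave 59 features higher and 1297 lower, all reads counted 77 and 1139, and library totals 2180 and 1021. The median log2 fold changes of all features were then -0.19, -0.06 and 0.76, against 0.18 with TMM. With size factors the CSR-1 type list had 0 genes higher and 6 lower and the pathway list 2 and 8. ERGO-1 targets had a median of -0.07 against A to F and 1.64 against G to I (16 of 19 higher), and histones -0.24 and 1.21 (21 of 26 higher). Intervals (-3.16 and -2.14) and WAGO genes (-2.50 and -1.69) were lower against both. Collagens were too, with 7 of 7 and 4 of 4 tested lower (-4.78 and -4.07), and pseudogenes had 26 of 33 and 16 of 29 lower (-1.53 and -1.18), with 1 and 7 higher. The CSR-1 type list had 9 higher and 2 lower of 37 against A to F and 13 and 11 of 35 against G to I, ribosomal proteins 8 and 0 of 41 and 4 and 4 of 30, and pathway genes 18 and 7 of 51 and 20 and 7 of 45. Of 3236 features tested against both sets, 696 were lower and 303 higher against each, and 84 were called in opposite directions. Without null B the calls of rps-30, the interval on X and the rise of mut-7 (398 CPM ± 16.6, log2 0.64, adjusted p = 0.00196) were lost, the last also with size factors and with all reads counted.

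DPF-3 S784A was compared with wild type to ask the same of a single residue of the protein. The groups that fell were again intervals, with 383 lower and 7 higher of 495 (median -2.30), WAGO genes, with 7 of 9 lower (median -2.13), and collagens, with 7 of 7 lower (median -4.57, or -3.97 with the gene at 0 taken at its bound). saeg-2 was at 303 CPM ± 99.9 against 5151 ± 1069 in wild type (log2 -4.11, SE 0.33, adjusted p = 1.21e-08), C38D9.2 at 645 ± 40.4 against 5302 ± 1818, his-24 at 1344 ± 142 against 9412 ± 3115 and eri-6 at 2516 ± 162 against 10329 ± 2241 (n = 3 and 9). No count was left of the interval on chromosome III (6630737 to 6631713; at least 21.6-fold lower) or H14A12.5 (III, 7467574 to 7469080; at least 15.6-fold). The same held for fbxb-56 (I, 14084512 to 14085525; at least 14.2-fold), col-38 (II, 8568035 to 8569088; at least 12.7-fold) and an interval that overlaps an exon of the pseudogene Y105C5A.2 (IV, 15556849 to 15557985; at least 15.8-fold). col-111 (IV, 4655791 to 4657974) had 3 counts against 2696, a ratio of 103 (95% interval 35.3 to 501). Against G to I alone the bounds were 11.9, 9.14, 7.64, 3.50 and 12.3 in the order given, and the ratio of col-111 was 60.3 (95% interval 20.6 to 293).

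Pseudogenes had 17 lower and 1 higher of 48 (median -0.88), histones 3 lower and 7 higher of 44 and ERGO-1 targets 1 lower (C08F11.7, log2 -3.84) and 6 higher of 20. Ribosomal proteins had 1 lower and 4 higher of 55, pathway genes 2 and 9 of 51, the CSR-1 type list 0 and 9 of 41 and neuron genes 1 and 0 of 5. Rises were led by lsl-1 at 303 CPM ± 31.2 against 61.7 ± 34.0 (log2 2.38, SE 0.34, adjusted p = 7.05e-06) and the ERGO-1 target Y116F11A.1 (V, 19730580 to 19732242; log2 2.13), followed by C50B8.5 (2.1), the muscle gene ketn-1 (2.06), Y116A8B.1 (1.99) and fog-1, a germline sex determination gene (1.89). Smaller rises came from rnr-1, a subunit of ribonucleotide reductase (1.33), rpl-32 (1.27), eri-3 (1.18) and cbd-1 (0.89).

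In total 393 features were higher and 1054 lower. Without any 1 library fewer were higher, 203, 148 and 187 without S784A A, B and C and 197 to 230 without each of the 9 wild-type libraries, while 940 to 1073 were lower. With wild type as 2 sets 757 were higher and 1212 lower. Adjusted over the list alone, the counts higher and lower were 14 and 392 for intervals, 0 and 7 for WAGO genes, 0 and 7 for collagens and 1 and 17 for pseudogenes. They were 6 and 3 for histones, 6 and 1 for ERGO-1 targets, 4 and 1 for ribosomal proteins, 8 and 2 for pathway genes, 8 and 0 for the CSR-1 type list and 0 and 1 for neuron genes. By camera intervals (adjusted p = 4.44e-32), WAGO genes (9.25e-06), collagens (1.65e-06) and pseudogenes (0.0102) were lower relative to other features. ERGO-1 targets (0.0187), histones (0.00835), ribosomal proteins (0.0102), pathway genes (0.00467) and the CSR-1 type list (0.00489) were higher. With an estimated correlation none passed, with adjusted p = 0.298 for intervals, 0.155 for WAGO genes, 0.200 for collagens, 0.569 for pseudogenes. It was 0.664 for ERGO-1 targets, 0.668 for histones, 0.312 for ribosomal proteins, 0.200 for pathway genes and 0.113 for the CSR-1 type list. Neuron genes did not pass at the preset correlation (adjusted p = 0.913), and their median (-0.25) and the test differed in sign.

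Size factors gave 70 features higher and 1172 lower, all reads counted 40 and 1141, and library totals 1576 and 890. The medians of all features were -0.25, -0.47 and 0.61 against 0.04 with TMM. With size factors ERGO-1 targets had 1 higher and 1 lower, pathway genes 2 and 7 and ribosomal proteins 1 and 1. Against A to F and G to I the medians were -0.02 and 1.65 for ERGO-1 targets, 0.04 and 1.62 for histones, -2.72 and -1.71 for intervals and -2.38 and -1.49 for WAGO genes. Collagens had 7 of 7 and 4 of 4 lower, and pseudogenes 21 of 33 and 14 of 29 lower (-0.68 and -0.12), with 1 and 10 higher. Genes of the CSR-1 type list were 10 higher and 0 lower against A to F and 14 and 7 against G to I, ribosomal proteins 2 and 0 and 5 and 4, and pathway genes 8 and 5 and 17 and 5. The folds against the 2 sets were 3.84 and 10.7 for lsl-1, 3.06 and 8.34 for C50B8.5, 10.1 and 4.49 for C38D9.2 and 8.50 and 4.14 for his-24. In wild type ketn-1 had 46.5 CPM in A to F and 4 in G to I, fog-1 110 and 10.0, Y116A8B.1 192 and 29.2, Y116F11A.1 79.6 and 10.2 and egl-21 193 and 37.3. Of 3236 features tested against both sets, 650 were lower and 188 higher against each, and 51 were called in opposite directions. Leaving out S784A B ended the calls of Y116F11A.1, fog-1, ketn-1 and egl-21 (log2 -2.51). Leaving out S784A A ended those of fog-1, ketn-1 and egl-21, S784A C those of ketn-1, egl-21 and rpl-32, and wild type B that of ketn-1. With size factors fog-1 and ketn-1 were not called, and with all reads counted rnr-1, rpl-32, eri-3 and cbd-1 were not.

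The dpf-3 null and DPF-3 S784A were compared directly to ask whether losing the protein and changing 1 residue differ. Only 2 of 5038 features were called, both lower in the null. dpf-3 itself had 8.84 CPM ± 4.12 in the null and 139 ± 26.2 in S784A (n = 3 each; log2 -3.81, SE 0.45, adjusted p = 7.99e-05). ZC15.10 (WBGene00045050; V, 20310736 to 20311656) had 137 CPM ± 14.5 in the null, 567.7 ± 14.2 in S784A and 759 ± 89.2 in wild type (log2 -2.04, SE 0.30, adjusted p = 0.00164), a call lost without null B and when libraries were scaled to all reads counted. Before adjustment 247 features had a p under 0.05, and DESeq2 called 4. No list had a called member over all features except dpf-3 in the pathway list, and 89.3% of features lay within 2-fold. A muscle gene, 1 of 3 tested, was also lower adjusted over the list alone. The list medians were -0.35 for intervals, -0.04 for ERGO-1 targets, 0.01 for WAGO genes (mean -0.10, the sign of the test), 0.49 for collagens (0.14 with the gene at 0 at its bound), and -0.29 for histones. They were -0.15 for pseudogenes, 0.26 for ribosomal proteins, 0.08 for pathway genes, -0.04 for the CSR-1 type list (mean 0.02) and -0.15 for neuron genes. By camera the interval (adjusted p = 1.74e-08), histone (0.0169) and pseudogene (0.00467) sets were lower in the null, with adjusted p = 0.622, 0.694 and 0.515 with an estimated correlation. The other lists did not pass (lowest adjusted p = 0.167, ribosomal proteins).

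The count of 2 depended on how the spread was estimated, since the 9 wild-type libraries enter the fit. With wild type as 2 sets 134 features were called, 30 of them higher and 34 of the lower ones intervals, and with only the groups compared 140 were called. Both fits take the spread within a set or genotype only. A difference like that between the wild-type sets would therefore be called as well.

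**Figure D2:**
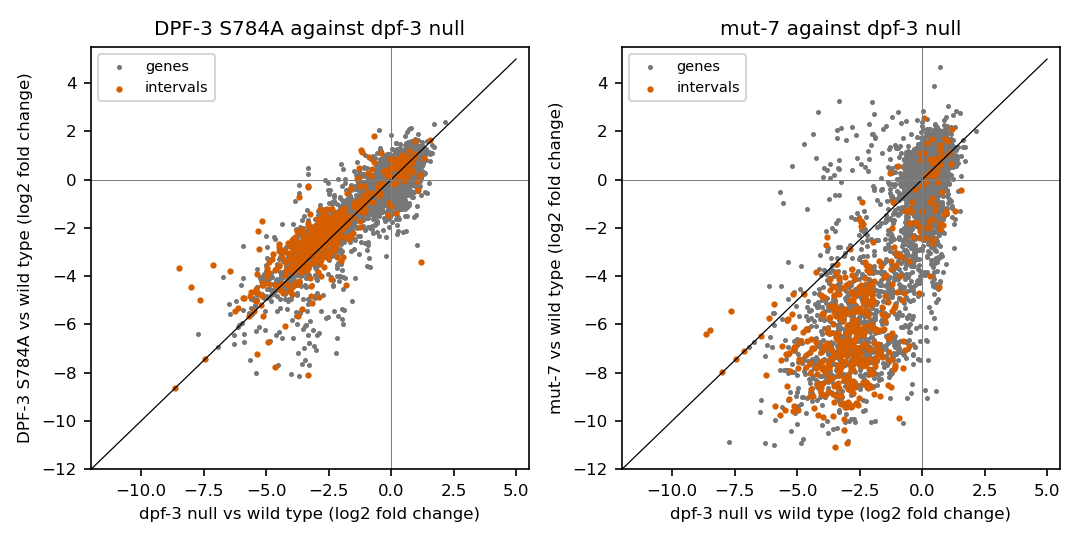
Log2 fold changes against wild type of each tested feature in the dpf-3 null and DPF-3 S784A (r = 0.899) and in the dpf-3 null and mut-7 (r = 0.821). Grey points are genes, orange points intervals, and the diagonal marks equal changes.

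mut-2 was compared with wild type to measure the small RNAs that depend on the mutator pathway. All 9 WAGO genes and all 7 collagens fell, with medians of -3.94 and -5.23 (-5.12 with zeros at their bound), as did 440 of 495 intervals (median -5.08, or -4.04 with zeros at their bound), 32 of 44 histones (median -2.52, or -2.21) and 16 of 20 ERGO-1 targets (median -3.20). C44B11.6 (WBGene00016635; III, 3153148 to 3153336), an ERGO-1 target, fell from 5580 CPM ± 1727 to 282 ± 31.4 (log2 -4.30, SE 0.35, adjusted p = 1.53e-09), saeg-2 from 5151 ± 1069 to 163 ± 60.3, bath-45 (II, 13123020 to 13125189) from 6486 ± 1366 to 426 ± 118 and his-24 from 9412 ± 3115 to 246 ± 204 (n = 3 and 9). In the small RNA pathway eri-6 fell 39.9-fold to 261 CPM ± 106 and parn-1, a ribonuclease gene of piRNA processing, from 1974 ± 344 to 268 ± 59.5. No count was left of Y110A7A.21 (I, 5110048 to 5111162; at least 45.5-fold lower), col-157 (V, 11484042 to 11485039; at least 41.8-fold), or C07G3.8 (V, 3498103 to 3502138; at least 39.8-fold). The same held for fbxa-60 (III, 944733 to 946300; at least 39.1-fold), an intergenic interval on I (2056871 to 2057320; at least 37.7-fold) and an interval over an exon of the pseudogene Y50E8A.14 (V, 14761618 to 14764280; at least 34.5-fold). Against G to I alone these 6 bounds were 31, 22.9, 22.7, 9.26, 20.8 and 6.45 in the order given.

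Rises included mes-3 (I, 4996835 to 5003202), a gene of germline chromatin silencing, from 17.8 CPM ± 6.46 to 147 ± 48.4 (log2 2.98, SE 0.36, adjusted p = 3.2e-07), rnf-1 (2.90), the sperm gene spe-12 (2.99), srt-17 (3.24; 155 CPM, against 24.3 in A to F and 3.39 in G to I) and C48B4.7 (3.41). egl-1, an activator of programmed cell death, had 9 counts against 2 in wild type, a ratio of 50.7 (95% interval 10.5 to 483), or 27.2 (5.63 to 259) against G to I, which held both counts. The folds against A to F and G to I were 5.49 and 16.5 for spe-12 and 49.4 and 24 for his-24. Pseudogenes had 31 lower and 1 higher of 48 (median -2.84, or -2.17 with zeros at their bound), and neuron genes 2 lower of 5. The CSR-1 type list had 1 lower and 4 higher of 41, with mcm-6 at 0.97 and oma-1 at 1.34, ribosomal proteins 2 and 4 of 55, and pathway genes 10 and 11 of 51.

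In total 809 features were higher and 1573 lower, or 952 and 1676 with wild type as 2 sets. Adjusted over the list alone, the counts higher and lower were 0 and 9 for WAGO genes, 0 and 7 for collagens, 21 and 449 for intervals, 2 and 33 for histones. They were 0 and 16 for ERGO-1 targets, 1 and 32 for pseudogenes, 1 and 0 for the CSR-1 type list, 0 and 1 for ribosomal proteins, 11 and 10 for pathway genes and 0 and 2 for neuron genes. By camera WAGO genes (adjusted p = 9.28e-09), collagens (0.000912), intervals (2.69e-32), histones (0.0187), ERGO-1 targets (4.19e-06) and pseudogenes (8.37e-06) were lower and ribosomal proteins (0.0231) higher relative to other features. With an estimated correlation none passed, with adjusted p = 0.104 for WAGO genes, 0.352 for collagens, 0.298 for intervals, 0.709 for histones, 0.380 for ERGO-1 targets, 0.315 for pseudogenes and 0.364 for ribosomal proteins. The CSR-1 type list (0.0521), pathway genes (0.161; median 0.19 and mean -0.26) and neuron genes (0.913) did not pass at the preset correlation.

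Size factors gave 367 features higher and 1741 lower, all reads counted 74 and 1764, and library totals 2525 and 1289. The medians of all features were -0.36, -0.76 and 1.17 against -0.02 with TMM. With size factors ribosomal proteins had 0 higher and 4 lower. Against A to F and G to I the medians were -3.55 and -2.19 for ERGO-1 targets, -3.18 and -1.28 for histones, -5.39 and -4.59 for intervals and -4.32 and -3.83 for WAGO genes. Collagens had 7 of 7 and 4 of 4 lower, and pseudogenes 30 of 33 and 24 of 29. In the CSR-1 type list 5 were higher and 3 lower against A to F and 6 and 9 against G to I, ribosomal proteins 8 and 1 and 2 and 2, and pathway genes 11 and 13 and 9 and 10. Of 3236 features tested against both sets, 908 were lower and 412 higher against each, and 23 were called in opposite directions. The call of oma-1 was lost without mut-2 C and that of rps-20 (log2 1.14) without mut-2 A. With all reads counted oma-1, rps-20 and mcm-6 were not called, and with size factors oma-1 and rps-20 were not.

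mut-7 was compared with wild type for the same purpose. Again all 9 WAGO genes and all 7 collagens fell (medians -4.02 and -7.44, or -3.80 and -5.80 with zeros at their bound), with 446 of 495 intervals (-6.34, or -4.73), 33 of 48 pseudogenes (-4.59, or -3.11), 30 of 44 histones (-1.64) and 13 of 20 ERGO-1 targets (-1.69). saeg-2 fell 107-fold to 46.0 CPM ± 23.1 (log2 -6.74, SE 0.40, adjusted p = 1.71e-11), eri-6 58.9-fold to 171 ± 65.4, his-24 to 70.3 ± 42.9, parn-1 to 221 ± 21 and C44B11.6 to 955 ± 36.6 (n = 3). bath-13 (II, 2520842 to 2522060) had 3 counts against 2730, a ratio of 149 (95% interval 51.1 to 725). No count was left of an interval in an intron of the pseudogene Y37H2A.16 (V, 18119905 to 18120626; at least 174-fold lower), dyf-3, a gene of sensory cilia (IV, 3396581 to 3399231; at least 159-fold) or the pseudogene AC8.12 (X, 239849 to 240781; at least 154-fold). The same held for an intergenic interval on V (8480110 to 8481492; at least 150-fold), col-111 (at least 148-fold) and B0261.8 (at least 141-fold). Against G to I alone these bounds were 122, 102, 111, 95.7, 86.2 and 70.4 in the order given, and the ratio of bath-13 was 115 (95% interval 39.1 to 557).

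mes-3 rose to 133 CPM ± 39.6 (log2 2.86, SE 0.32, adjusted p = 7.14e-08), with gmeb-3 (III, 3768500 to 3770328; 3.87), K09C6.8 (3.26), C44B9.2 (3.23) and C48B4.7 (3.03). egl-1 had 14 counts against 2, a ratio of 42.6 (95% interval 9.79 to 387), or 22.9 (5.25 to 207) against G to I. The folds against the 2 sets were 20.3 and 6.19 for C44B9.2 and 168 and 81.9 for his-24. The CSR-1 type list had 12 genes higher, with cbd-1 at 0.85, and 3 lower of 41, among the latter the P granule helicase glh-1, at 480 CPM ± 38.4 against 1012 ± 123 (log2 -1.07), which was 0.25 with library totals. Ribosomal proteins had 1 higher and 3 lower of 55, pathway genes 14 and 14 of 51 and neuron genes 0 and 3 of 5, with ida-1 at least 10.2-fold and egl-21 at least 13.7-fold lower (8.16 and 4.69 against G to I). In wild type gmeb-3 had 0 CPM in A to F and 4.74 in G to I, and K09C6.8 1.33 and 11.71.

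In total 1173 features were higher and 1670 lower, or 1475 and 1780 with wild type as 2 sets. Adjusted over the list alone, the counts higher and lower were 0 and 9 for WAGO genes, 0 and 7 for collagens, 12 and 448 for intervals, 0 and 33 for pseudogenes. They were 1 and 31 for histones, 1 and 13 for ERGO-1 targets, 6 and 2 for the CSR-1 type list, 0 and 1 for ribosomal proteins, 14 and 14 for pathway genes and 0 and 3 for neuron genes. By camera WAGO genes (adjusted p = 5.59e-08), collagens (0.000872), intervals (7.05e-37) and pseudogenes (1.27e-05) were lower and the CSR-1 type list (0.0433) higher relative to other features. With an estimated correlation none passed, with adjusted p = 0.104 for WAGO genes, 0.352 for collagens, 0.255 for intervals, 0.324 for pseudogenes and 0.200 for the CSR-1 type list. ERGO-1 targets (0.135), histones (0.0679), ribosomal proteins (0.128; median 0.14 and mean -0.15), pathway genes (0.380; median 0.21 and mean -0.34) and neuron genes (0.523) did not pass at the preset correlation.

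Size factors gave 416 features higher and 1882 lower, all reads counted 404 and 1625, and library totals 2933 and 1339. The medians of all features were -0.31, -0.07 and 1.36 against 0.11 with TMM. With size factors the CSR-1 type list had 1 higher and 9 lower, and with library totals ERGO-1 targets had 8 higher and 6 lower. Against A to F and G to I the medians were -2.27 and -0.46 for ERGO-1 targets, -2.15 and -0.83 for histones, -6.67 and -5.91 for intervals and -4.29 and -4.08 for WAGO genes. Collagens had 7 of 7 and 4 of 4 lower, and pseudogenes 29 of 33 and 20 of 29. The CSR-1 type list turned with the set, with 14 higher and 7 lower of 37 against A to F (median 0.26) and 6 and 13 of 35 against G to I (median -0.08). Ribosomal proteins had 3 higher and 1 lower and then 0 and 5, and pathway genes 13 and 15 and then 10 and 15. Of 3236 features tested against both sets, 937 were lower and 557 higher against each, and 55 were called in opposite directions. rps-17, with 1 count against 57 (ratio 9.36, 95% interval 1.61 to 376; 5.67, 0.88 to 238, against A to F and 12.5, 2.13 to 508, against G to I), was not called without mut-7 B or with library totals, and cbd-1 was not called with size factors.

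**Figure D3:**
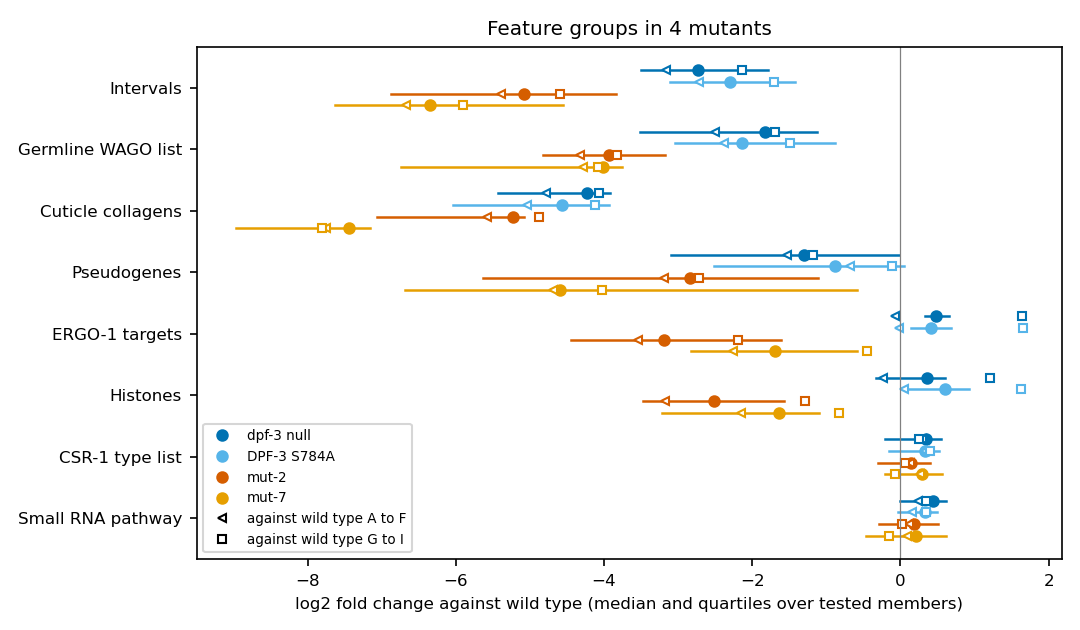
Median log2 fold change against wild type, with quartiles, of the tested members of 8 feature groups in each mutant. Filled circles use all 9 wild-type libraries, open triangles A to F and open squares G to I. ERGO-1 targets and histones shift with the wild-type set used, while intervals and the germline WAGO list are lower against both.

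Fixed lists with under 5 tested members were counted only. Of 4 tested spermatogenesis genes (64 in the table), 1 was higher and 1 lower in the dpf-3 null and in mut-2, and 1 was lower in DPF-3 S784A, in mut-7 and in the dpf-3 genotypes against the mut genotypes. Of 3 muscle genes (21 in the table), 1 was higher in DPF-3 S784A and in the dpf-3 genotypes against the mut genotypes, and 1 was lower in mut-2 and in mut-7. Of 3 intestine genes (20 in the table), 2 were lower in mut-2, 1 was lower in mut-7, and 2 were higher in the dpf-3 genotypes than in the mut genotypes. Over all features no member of these 3 lists was called in the comparisons not mentioned. With adjustment over the list alone, 1 sperm gene was also higher in mut-2 than in mut-7 and 1 muscle gene lower in the null than in S784A. Transposons, microRNAs, heterochronic microRNAs, the mir-35 family and piRNAs have 0 features in the table and were not analysed here. None of the camera calls at the preset correlation held with an estimated one in the fit with 1 wild-type group. With wild type as 2 sets and an estimated correlation, intervals, WAGO genes and collagens were lower in all 4 mutants (highest adjusted p = 0.0448, collagens in mut-7). ERGO-1 targets were then lower in mut-2 (adjusted p = 0.0212) and higher in the dpf-3 genotypes than in the mut genotypes (adjusted p = 0.00461), as were histones (adjusted p = 0.00963). WAGO genes, pseudogenes and intervals were also higher in the dpf-3 than in the mut genotypes. ERGO-1 targets were lower in mut-2 than in mut-7, and intervals lower in the null than in S784A (adjusted p under 0.05 by camera for each).

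mut-2 and mut-7 were compared to ask whether these 2 genes differ. Of 20 ERGO-1 targets 5 were called lower in mut-2 than in mut-7 and 0 higher, with a median of -1.62. In this fit the list was lower by camera at the preset correlation but not with an estimated one (adjusted p = 0.113). C44B11.6 had 282 CPM ± 31.4 in mut-2 and 955 ± 36.6 in mut-7, and F55C9.3 (V, 19287009 to 19288173) 189 ± 77.5 in mut-2. Among the largest differences, acdh-1 (I, 6497436 to 6499560), an acyl-CoA dehydrogenase gene, had 0 counts in mut-2 and 61 in mut-7 (at least 11-fold lower, adjusted p = 0.00239), his-9 (II, 13823648 to 13824058) 0 and 37 (at least 6.66-fold) and F25E5.1 (V, 7465884 to 7471288) 0 and 33 (at least 5.94-fold). Higher in mut-2 were jmjc-1 (I, 3631091 to 3636485), with 29 counts against 3 (ratio 17.9, 95% interval 5.55 to 91.8, adjusted p = 0.0054), C34F6.7, with 11 against 0 (at least 6.79-fold), and ugt-31, with 6 against 0 (at least 3.70-fold). In mut-2 A, B and C they had 5, 2 and 22 counts (jmjc-1), 2, 1 and 8 (C34F6.7) and 3, 1 and 2 (ugt-31). Each was more abundant in wild type than in mut-7, as were the features of which mut-2 A and C held more than B. For those features carry-over of wild-type reads stays open, as given below, so a difference between the genotypes is not settled here.

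In total 20 features were higher and 23 lower in mut-2 than in mut-7, and 559 had a p under 0.05 before adjustment. All reads counted gave 21 and 67, library totals 49 and 39, DESeq2 97 and 28, and wild type as 2 sets 142 and 100. Adjusted over the list alone, 2 ERGO-1 targets were higher and 14 lower, 2 WAGO genes higher, 1 histone lower, 3 pseudogenes higher and 2 lower and 4 intervals higher. By camera ERGO-1 targets (adjusted p = 7.57e-23) were lower in mut-2 and intervals (4 called higher, median 0.73, adjusted p = 2.3e-05) higher, with adjusted p = 0.113 and 0.684 with an estimated correlation, and the other lists did not pass (lowest adjusted p = 0.0578, histones). Their medians were -0.38 for histones (1 lower), 0.47 for WAGO genes, 2.22 for collagens (0.89 with zeros at their bound), 0.77 for pseudogenes (1 higher, 1 lower), -0.14 for the CSR-1 type list, 0.19 for ribosomal proteins, 0.02 for pathway genes and 0.25 for neuron genes. With all reads counted the medians of WAGO genes, ribosomal proteins and pathway genes were below 0. Leaving out mut-2 B gave 90 calls, 76 of them higher, and leaving out mut-2 A, mut-2 C, mut-7 A, B or C gave 12, 14, 13, 12 and 27. Without mut-2 A the calls of C34F6.7, ugt-31, his-9 and F25E5.1 were lost, without mut-2 C these and jmjc-1, and without mut-2 B that of F25E5.1. Without mut-7 A all 6 but jmjc-1 and acdh-1 were lost, without mut-7 B C34F6.7, ugt-31, F25E5.1 and jmjc-1, and without mut-7 C C34F6.7 and ugt-31. With all reads counted jmjc-1 and ugt-31 were not called.

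The mean of both dpf-3 genotypes was compared with the mean of mut-2 and mut-7 to ask where the kinds of mutant differ. Wild type does not enter this contrast, which therefore does not control for the difference between its sets. Nearly all features of the ERGO-1 list (19 of 20, median 2.87) and the histones (37 of 44, median 2.51) were higher in the dpf-3 genotypes, as were 8 of 9 WAGO genes (2.58), 343 of 495 intervals (2.97, or 2.52 with zeros at their bound; 10 lower) and 30 of 48 pseudogenes (2.36). fbxa-61 (III, 1239048 to 1242799), an F-box gene, had 4323 CPM ± 1204 in the dpf-3 genotypes and 7.51 ± 9.16 in the mut genotypes (n = 6 each; log2 9.2, SE 1.00, adjusted p = 3.67e-07). The interval over the pseudogene Y50E8A.14 had no count in the mut genotypes (at least 97.3-fold higher) as had fbxa-60 (at least 82.5-fold). Lower in the dpf-3 genotypes were Y37E11B.10 (IV, 3603550 to 3606466), with 0 counts against 40 (at least 18.4-fold), cbs-2 (II, 2220396 to 2223567), with 2 against 66 (ratio 45.6, 95% interval 12.1 to 384), and ZK616.65 (IV, 5408386 to 5411220), with 1 against 44 (ratio 60.8, 95% interval 10.4 to 2450). In wild type these 3 genes had 0, 2.47 and 1.07 CPM in A to F and 25.8, 107 and 54 in G to I. For these 3 genes a genotype difference cannot be told apart from the difference between the sets. The 3 features higher in the dpf-3 genotypes also followed the sets, being higher in A to F than in G to I. fbxa-61 had 6765 and 661 CPM, the interval over Y50E8A.14 996 and 93.2 and fbxa-60 1111 and 135. Part of their folds thus cannot be told apart from the difference between the sets. The mut genotypes lay below G to I as well, with 7.51 CPM of fbxa-61 and no count of the interval or fbxa-60.

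In total 1400 features were higher and 380 lower in the dpf-3 genotypes, 1160 and 1640 with library totals, and 1430 and 144 with all reads counted. Adjusted over the list alone, the counts higher and lower were 19 and 1 for ERGO-1 targets, 40 and 1 for histones, 8 and 0 for WAGO genes, 373 and 15 for intervals. They were 30 and 0 for pseudogenes, 3 and 0 for collagens, 17 and 7 for pathway genes, 5 and 0 for ribosomal proteins, 5 and 0 for the CSR-1 type list and 3 and 0 for neuron genes. By camera ERGO-1 targets (adjusted p = 7.04e-15), histones (1.36e-08), WAGO genes (1.25e-07), intervals (4.77e-16) and pseudogenes (5.33e-06) were higher, and none held with an estimated correlation (adjusted p = 0.200, 0.364, 0.104, 0.463 and 0.309). Collagens (3 of 7 higher, median 2.31, or 1.79 with zeros at their bound) and pathway genes (17 higher, 7 lower, median 0.10) did not pass. Neither did ribosomal proteins (6 higher, median 0.13, the test below 0), the CSR-1 type list (5 higher, 1 lower, median 0.04, mean -0.02) or neuron genes (2 higher, median 2.37; lowest adjusted p of the 5 lists 0.352). With library totals the medians of pathway, ribosomal and CSR-1 type genes turned to -0.55, -0.48 and -0.60. Since the labels do not place mutants with a wild-type set, the contrast was also taken as the dpf-3 genotypes against A to F less the mut genotypes against G to I. That gave 1321 features higher and 393 lower, with 13 of 20 ERGO-1 targets (median 1.04), 16 of 44 histones (1.04), 5 of 9 WAGO genes (1.73; 1 lower), 252 of 495 intervals (1.98; 35 lower) and 24 of 48 pseudogenes (1.46; 2 lower) higher. With the pairing reversed, 1770 features were higher and 763 lower. Higher were then 19 of 20 ERGO-1 targets (median 4.90, 1 lower), 43 of 44 histones (3.99) and 9 of 9 WAGO genes (2.42). So were 434 of 495 intervals (4.09, 6 lower) and 35 of 48 pseudogenes (3.31, 2 lower). The call of cbs-2 was lost without S784A C or mut-2 B and that of ZK616.65 without mut-2 A, and neither was called with all reads counted.

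**Figure D4:**
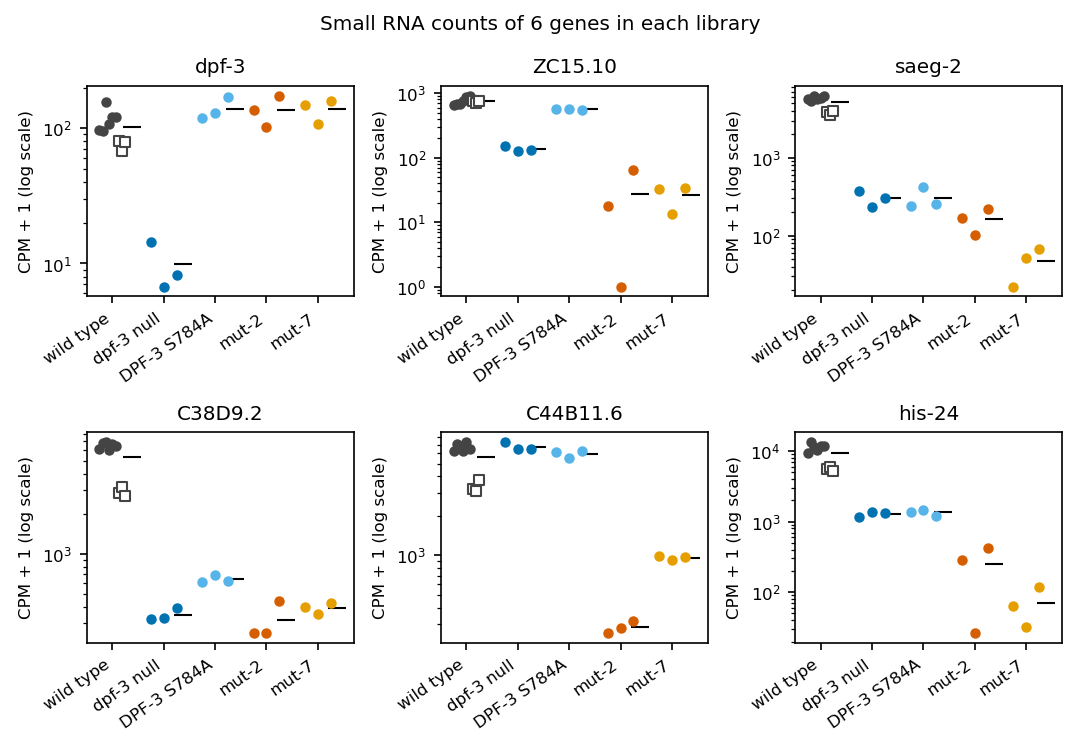
Small RNA counts of 6 genes as CPM + 1 on a log axis, per library. Filled circles are libraries, open squares wild type G to I, and bars are means. dpf-3 is at 8.84 CPM in the null, saeg-2 at 5151 in wild type and 46.0 in mut-7, and C44B11.6 at 282 in mut-2 and 955 in mut-7.

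The changes against wild type were compared between mutants across the 5038 features, which are not independent replicates and share the 9 controls. Features that fell in both dpf-3 genotypes numbered 1014, 382 of them intervals, and 1002 of these, with 381 intervals, fell in mut-2 and mut-7 too. Both mut genotypes shared 1489 falls, of which 356 (38 intervals) were not called lower in either dpf-3 genotype. Another 5 features fell in both dpf-3 genotypes and in neither mut genotype. Rises in all 4 mutants numbered 124 with TMM scaling. This number depends on the scaling, since only 59 features rose in the null with DESeq2 size factors. With all reads counted only 40 rose in S784A. The simulated groups given next were drawn around the mean of all 9 wild-type libraries. Each part of the split wild type held libraries of both sets. Neither therefore removes agreement that mutants would share by resembling the same wild-type set. For the dpf-3 null and DPF-3 S784A Pearson's r was 0.899 (0.0872 in simulations of unchanged groups, 0.894 and 0.869 with wild type split between the comparisons). The covariance was 2.28 (simulated 0.0191), and the shared falls compare with 242 if calls were independent and 966 and 950 with wild type split. For mut-2 and mut-7 r was 0.889 (simulated 0.0858, split 0.880 and 0.888). The covariance was 7.79 (simulated 0.0238), and the shared falls compare with 521 and with 1434 and 1427. Between a dpf-3 and a mut genotype r was 0.782 and 0.821 for the null with mut-2 and mut-7 and 0.698 and 0.714 for S784A, against simulated values of 0.0715, 0.0813, 0.0763 and 0.0842 and split values from 0.672 to 0.828. The covariances were 3.47, 4.15, 3.06 and 3.57 (simulated 0.0176, 0.0158, 0.0240 and 0.0208). Shared falls were 1119, 1133, 1027 and 1031, against 362, 384, 329 and 349 if independent and 970 to 1098 with wild type split.

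Since the strand setting of the counts is not given, counts of overlapping genes cannot be assigned with certainty. This concerns eri-6 (with T01A4.9 and, on the other strand, sosi-1), Y110A7A.21 (with Y110A7A.15 and aap-1), col-111 (psr-1), H14A12.5 (fum-1), jmjc-1 (cah-6), parn-1 (frpr-15), mcm-6 (srxa-10), rpl-32 (chmp-7), ketn-1 (F54E2.2), C44B9.2 (C44B9.3) and rps-20 (mir-354). Noncoding RNA genes on the other strand overlap saeg-2 (T23G5.9 and T23G5.10), his-24 (M163.16 and M163.19), col-71 (Y49F6B.15), cbs-2 (F54A3.10) and spe-12 (T02E1.9). Reads shared between paralogs concern the histone and F-box genes.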

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

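The test of a batch by labels, the test of counting noise, the tests of scaling and of the wild-type sets for the ERGO-1 pattern, the splits into other groups, and the analyses with wild type as 2 sets or as A to F were chosen after the results were seen.

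Wild-type libraries G to I stood apart from A to F, with 2598 of 5038 features called between the sets, and no biological explanation was tested because the labels give none. A difference in depth is argued against, since with all 9 libraries thinned to 233040 counts the lowest correlation within a set still exceeded the highest between the sets by 0.144. A few abundant features are argued against too, since 52.94% of the remaining features were called after the 100 most abundant had been removed. A library or growth batch cannot be told apart from other causes, since 0 label sets occur in G to I and not in A to F. When G to I were put in a mutant's place, 902, 1187, 698 and 414 features were called with the libraries of the null, S784A, mut-2 and mut-7 comparisons, against 1829, 1447, 2382 and 2843 with the real groups.

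ERGO-1 targets, the class of the ERGO-1 Argonaute, were higher in the dpf-3 genotypes than in mut-2 and mut-7, with 19 of 20 called and a median of 2.87. Scaling is argued against, with at least 18 called under 4 scalings, and so is depth, with 19 called after thinning to 40693 counts. If the dpf-3 libraries share what sets A to F apart and the mut libraries what sets G to I apart, the members called when each kind is compared with its own set would be few, and 13 were called. For the other 7 members that link stays open, because the labels do not place the mutants with a set, and leaving wild type out of the fit (19 called) tests no mixture of its sets, since wild type does not enter the contrast. A genotype difference in these small RNAs may account for the 13, a hypothesis found and tested on the same data. The contrast averages mut-2 and mut-7, which differed. Against G to I 16 of 19 tested members were lower in mut-2 (median -2.19) and 9 of 19 in mut-7 (median -0.46), with 1 higher in each. The 13 were not tested for each mut genotype alone, so they may rest more on mut-2.

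Libraries A and C of mut-2 held more of 393 features abundant in wild type and near 0 in mut-7 than B, with 280, 83 and 444 counts in A, B and C (0.688%, 0.166% and 1.05% of feature counts, 10.4% in wild type). Counting noise is argued against for independent reads only, by a simulated exact multinomial test (p = 1e-04, the smallest it can give), and it is not given whether reads are independent molecules. Carry-over of wild-type reads stays open, since the 2 libraries differ. Against the proportions of wild type A to F chi-square per degree of freedom was 1.402 for A and 3.006 for C, and against G to I 1.465 and 2.439, all above the 95% level of simulations (at most 1.153). A biological difference between mut-2 replicates was not tested.

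With the libraries split into other groups of the same sizes, 1 of 100 splits, the real one, gave as many calls in each of the 4 comparisons with wild type and in the contrast of dpf-3 and mut genotypes. Other splits mix genotypes within a group, and their median was 0 calls. Fewer calls were thus likely in advance, so these splits do not exclude other causes, the difference between the wild-type sets among them. The highest other counts were 902 against 1829 for the null, 1 against 1447 for S784A, 698 against 2382 for mut-2, 0 against 2843 for mut-7 and 739 against 1780 for the contrast, and the counts of 902 and 698 are the split that follows the wild-type sets, which was not among the splits drawn for S784A and mut-7. For the null against S784A (2 against 0) and mut-2 against mut-7 (43 against 3) the 10 splits are too few for a share under 0.05.

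Of 91 measures of the 9 wild-type libraries tested for a library far from the others, 3 had one, where chance gives about 1 in 20. They were rnr-1 in wild type D, at 99.22 CPM with the next at 70.7, egl-1 in wild type G, at 4.047 CPM with the others at 0, and K09C6.8 in wild type I, at 23.2 CPM with the next at 8.00.

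Differences between mutants passed a direct test as given here, for lists by camera at the preset correlation. Some lists also passed with an estimated correlation when wild type entered as 2 sets (adjusted p under 0.05). These were intervals between the null and S784A, ERGO-1 targets between mut-2 and mut-7, and all lists given between the dpf-3 and the mut genotypes. The values with an estimated correlation printed next are from the fit with 1 wild-type group. Between the null and S784A the log2 fold changes were -3.8134 for dpf-3 and -2.0409 for ZC15.10, and the interval median was -0.3526 (adjusted p = 0.622 by camera with an estimated correlation), with histones at -0.29 (0.694) and pseudogenes at -0.15 (0.515). Between mut-2 and mut-7 they were -1.757 for C44B11.6, -2.2974 for F55C9.3, -7.1755 for his-9, 6.2881 for C34F6.7, 5.4155 for ugt-31, 4.0814 for jmjc-1, -7.844 for acdh-1 and -6.9857 for F25E5.1 (fitted values, which are no bounds for genes at 0), and the ERGO-1 median was -1.616 (adjusted p = 0.113 with an estimated correlation), with intervals at 0.73 (0.684). Between the dpf-3 and the mut genotypes 1780 features differed, with medians of 2.87 for ERGO-1 targets, 2.579 for WAGO genes, 2.509 for histones, 2.357 for pseudogenes and 2.967 for intervals. With an estimated correlation these lists did not pass in the fit with 1 wild-type group (adjusted p = 0.200, 0.104, 0.364, 0.309 and 0.463 by camera).

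Reads in no feature entered the tests of shares and the scaling to all reads counted, but not the tests of features or lists. They made up more of the reads counted in each mutant (78.98% in the null, 82.22% in S784A, 90.27% in mut-2 and 86.08% in mut-7) than in any wild-type library (at most 71.3%).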

How the results depend on the processing

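Alternatives with wild type as 2 sets or as A to F, scaling to all reads counted, libraries A to C without a block and the mut-2 libraries left out were chosen after seeing the data. Under the 3 other scalings 1174 to 1692 of the 1829 calls of the null were kept, 1073 to 1282 of 1447 for S784A, 1642 to 2098 of 2382 for mut-2 and 1999 to 2512 of 2843 for mut-7. Library totals moved the counts to 3201 calls for the null, 2466 for S784A, 3814 for mut-2, 4272 for mut-7, 6 for null against S784A, 88 for mut-2 against mut-7 and 2800 for the contrast of dpf-3 and mut genotypes, and with these totals glh-1 in mut-7 reversed to 0.25. All reads counted gave 1216 for the null and 88 for mut-2 against mut-7. Without a filter on low counts 87 features were higher and 1823 lower in the null and 70 and 1422 in S784A. In mut-2 they were then 169 and 2691 and in mut-7 209 and 3299. With calls of at least 2-fold only, the null had 124 higher and 1122 lower and S784A 121 and 1026. mut-2 had 495 and 1544 and mut-7 616 and 1625. The small counts moved with the filter, the method and the choice and grouping of libraries in the fit. Null against S784A gave 12 without a filter, 4 with a filter of 10 CPM, 4 with DESeq2, 140 with only the groups compared, 134 with wild type as 2 sets and 1 to 2 leaving out 1 library. mut-2 against mut-7 gave 92 without a filter, 125 with DESeq2, 8 with limma-voom, 87 with only the groups compared, 242 with wild type as 2 sets, 12 to 90 leaving out 1 library and 8 without mut-2 A and C, where mut-2 is 1 library and the spread comes from the other groups. The contrast gave 1113 with limma-voom. Letters do not pair the libraries (r of -0.0461 to 0.0598 over 30 pairs), and a block of letters A to C gave 103 and 217 calls for the 2 comparisons of mutants, against 107 and 223 without it. Against wild type G to I alone the differences in interval share were -9.447, -7.623, -10.25 and -12.95 percentage points, where no exact test can pass. The cause was not tested for these. Of 70 list results 38 lost their call with an estimated correlation, and 14 with wild type as 2 sets and an estimated correlation. Of 131 named results, 126 of them called, 21 lost the call leaving out 1 library and 23 under another scaling, and all kept their side with wild type as 2 sets. Scaling by microRNAs could not be run, since the table has none, and neither could removing rRNA and tRNA. The level equal to 3 counts was highest in mut-2 A, at 50.7 CPM, while in the dpf-3 null it lay within the range of the wild-type libraries.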

Other observations

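The features named next were chosen after their values were seen, and the link between dpf-3 and mut genotypes below was tested as a hypothesis of this re-analysis. With wild type as 2 sets, 134 features differed between the dpf-3 null and DPF-3 S784A, 30 of them higher in the null. The spread of that fit (common dispersion 0.00466) comes only from libraries within a set or genotype. The same fit called 2598 of 5038 features between the 2 wild-type sets. A difference of that kind between the dpf-3 groups would be called too, so its p-values do not establish a difference of genotype. Single genes are given next, and neither muscle nor F-box genes were tested as a group on these calls. unc-54 (I, 14855901 to 14863482), the main body wall myosin, had 138 CPM ± 1.17 in the null and 475 ± 172 in S784A (n = 3 each; log2 -1.74, SE 0.23, edgeR adjusted p = 3.86e-11) against 197 ± 112 in wild type. ttn-1 (V, 6120909 to 6202632), a titin-like protein, had 288 ± 56 and 628 ± 102 (log2 -1.17, adjusted p = 1.39e-07), and ketn-1 (V, 2781939 to 2807860), a kettin-like protein, 20.5 ± 2.92 and 121 ± 36.6 (log2 -2.57, adjusted p = 2.86e-05). Of F-box genes, fbxa-136 had 68.6 CPM in the null against 301, fbxa-166 45.7 against 236, fbxb-97 80.8 against 292 and fbxa-61 5398 against 3248. B0001.5 (IV, 12141165 to 12143331) was higher in the null, with 457 CPM against 140. Of these genes ketn-1 and fbxa-61 were also named by the fixed rule, and none was called between the dpf-3 genotypes with wild type as 1 group.

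Small RNAs that fell without DPF-3 function may belong to those that the mutator pathway makes. If so, features that fell in both dpf-3 genotypes should also fall in both mut genotypes when the comparisons share no wild-type library. Of 956 such features 944 did (98.74%), and of 971 with the wild-type libraries exchanged 963 did (99.18%), against 28.48% and 28.74% of all features tested. Each part of wild type held libraries of both sets, so a shared difference from that mixture is not removed. Features with more counts may be called more easily in every mutant, which could raise these shares as well and was not tested. The comparison does not show how the falls arise.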
